A study of Mus musculus with 20 samples.

How the data were processed

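Total RNA from extraocular and leg muscle of control and mdx mice was hybridised to one-colour Affymetrix arrays, 5 per group. The authors deposited a linear intensity per probe set and array. The software that summarised and scaled the arrays is not given in the sources used here; per the labels, the mdx arrays followed the standard Affymetrix protocol. The deposited intensities run from 0.4 to 95476.8, are never negative, and have a 2% trimmed mean of 1500.1 on each of the 20 arrays, so the authors had scaled them. The file holds 12654 probe sets, 66 of them Affymetrix controls. No pair of arrays had identical values.

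Each array was multiplied by 1 factor so that the 2% trimmed mean of the 12588 non-control probe sets was 500. Values under 50 were set to 50, which understates folds of dim genes, and log2 was taken. Signals in the text are means ± SD of scaled values before that floor, while folds come from the log2 values. Where any array of the dimmer group lay at the floor, the fold is written as at least. Such a bound is on the ratio of geometric means, and any fold can exceed the ratio of the means printed beside it. The 7204 probe sets that reached 200 on at least 5 arrays were tested. The platform annotation gave 1 gene symbol for 10298 probe sets and several for 363, and did not list 1993, which are unnamed here. Of the tested probe sets 6262 had 1 symbol, for 5468 distinct genes. Gene identifiers of 10279 probe sets were found in a RefSeq gene table, and 0 symbols changed.

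In limma 3.58.1 under R 4.3.3, lmFit and eBayes with an intensity trend were fitted to all 20 arrays as 4 groups, with 16 residual degrees of freedom and no covariate. There were 5 contrasts: mdx minus control in each muscle, their difference, and extraocular minus leg muscle in each genotype. Benjamini-Hochberg adjustment ran within each contrast, at 5%. Gene lists, 33 in number, were fixed before the data were examined; each gene was represented by its brightest tested probe set. The 31 lists with at least 4 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Members were also adjusted over the list alone.

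Genes are named by a rule fixed with the lists: per contrast the 8 largest increases and 8 largest decreases that passed and whose groups did not overlap (4 and 4 between muscles in mdx mice, no overlap rule for the difference of effects), up to 4 members with the smallest adjusted p per list described, and Dmd, Utrn and the sarcomeric myosin heavy chains. Only probe sets with 1 symbol are named. The probe set names are those of an early mouse array design, some of whose probe sets were later withdrawn by the maker. No list of these was among the sources used here and none was removed, so a named probe set, or one that did not pass, may not measure its gene. The genes given for the array labelled leg control 4 were chosen after its values were seen. Quality measures used a two-sided exact permutation test over 252 splits; 12 such comparisons were made, and after Benjamini-Hochberg adjustment the leg beta-actin difference had p = 0.0316.

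Alternatives were the values as deposited, quantile normalization, floors of 20 and 100, a pseudocount of 50, no filter and a filter at 500, no intensity trend, array weights, only the groups compared, a replicate block, the mean of all probe sets of a gene, and leaving out each array. A fit without leg control 1 and 4 was added after seeing the data. Leg control 1 had the lowest mean correlation with its own group (0.892, others 0.903 to 0.919) and a slow fibre score of 12.99, against 11.60 to 11.68 on arrays 2, 3 and 5.

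The fit was tested on simulated data, 10 draws of 7204 probe sets with 200 changed. With 1 spread per probe set in all groups it recovered 26.9%, 66.7% and 93.8% of changes of 1.5, 2 and 4-fold in the leg comparison, and 5.18% of its calls were of unchanged probe sets. In the extraocular comparison it recovered 22.5%, 66.4% and 93.0%, with 5.02% of calls unchanged. When each muscle kept its own spread per probe set, as estimated from these arrays, 13.9% of the leg calls and 10.0% of the extraocular calls were of unchanged probe sets, so a nominal 5% can understate the share of false calls where spreads differ between muscles. The list test found a list shifted by -0.5 log2 units and called 0 of the others. Genes were simulated independently in a single draw, so this does not test false list calls where the genes of a list are correlated.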

Results

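Transcript levels were measured in 2 kinds of skeletal muscle from 8-week-old mice: extraocular muscle, which moves the eye, and leg muscle of the hindlimb. Mice were wild-type controls or mdx mice, which carry a nonsense mutation in Dmd, the gene of the membrane-linked protein dystrophin, and model Duchenne muscular dystrophy. Each of the 4 groups held 5 one-colour Affymetrix arrays, 20 in all. The labels call the arrays of a group replicates without saying whether each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical. Between 47.2% and 52.0% of probe sets reached a scaled signal of 200 on each array. The number of arrays limits the precision of every value. The first 2 principal components held 22.0% and 18.1% of the variance; the first parted the muscles and the second parted leg control from leg mdx arrays.

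Dmd itself, read first, was lower in mdx arrays. In extraocular muscle its signal was 119 ± 31.7 (SD, n = 5) in mdx and 268 ± 47.4 in control arrays, with all 5 mdx arrays below all 5 controls (log2 difference -1.19, limma adjusted p = 0.233). In leg muscle it was 77.5 ± 32.3 against 149 ± 40.2 (log2 difference -0.92 with 1 mdx array at the floor, limma adjusted p = 0.0323), a call that ended in 6 of the 10 fits that each left out 1 array, with an adjusted p of up to 0.0942 (without leg control 1), and also with a floor of 100 (0.176). A nonsense mutation need not remove the transcript, so this signal is no strict check of the labels. The Y-linked gene Eif2s3y lay between 354 and 556 on every array.

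The array labelled leg control 4 had a signal of 45.2 for Myl2 and 445 for Myh7, slow-fibre myosin genes that lay between 8608 and 20220 and between 4040 and 14240 on the other 4 leg control arrays. Hoxd8, a gene of trunk and limb position, was at 94.9 on this array against 737 to 1416 on the others and 166 to 212 on the extraocular control arrays. Bpifa2, a secreted protein of salivary glands, was at 8892 against 78.1 to 828. The array was kept, as the design had fixed, and the counts of passing probe sets that involve leg controls are also given without it.

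The first comparison asked what differs between mdx and control mice in leg muscle. Among probe sets with 1 gene symbol, genes of macrophages and of the extracellular matrix held the largest increases. Lgals3, a macrophage lectin, was at least 45.8-fold higher in mdx leg muscle (3149 ± 624 against 60.9 ± 46.6, limma adjusted p = 3.14e-09). Postn, a matrix protein of tissue repair, was 22.3-fold higher (7638 ± 1200 against 362 ± 143), and Ctss, a lysosomal protease of macrophages, 21.2-fold higher (8856 ± 756 against 423 ± 88.0, limma adjusted p = 6.23e-13). Cd53 and Mmp12 were at least 23.1-fold and at least 22.3-fold higher, and Ccl8, Ccl2 and Lyz2 between 16.7 and 18.8-fold. The largest decreases were of Rpl41 (log2 difference -3.46), the carboxylesterase Ces1d (at least 6.55-fold), the signalling protein Wnt4 (at least 5.95-fold), the receptor Crhr2 (at least 4.71-fold), the water channel Aqp4 (4.08-fold) and Erdr1 (3.70-fold). Lppos and Gdap1 fell by at least 1.65 and by 1.56 on the log2 scale; the Lppos call ended in 1 of the 10 fits without 1 array (adjusted p = 0.0576). The probe sets of Rpl41, Ces1d and Erdr1 are of a kind shared within a gene family. That the 5 mdx arrays did not overlap the 5 controls was a condition for choosing these 16 genes.

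Several groups of immune genes rose in mdx leg muscle. Of 30 tested macrophage and myeloid genes, 29 rose and 0 fell, also when adjusted over the list alone (median log2 difference 2.24, camera adjusted p = 1.95e-35, and 0.00154 with an estimated correlation). Laptm5 was 12.9-fold and Mpeg1 8.40-fold higher. Of 16 cytokine and chemokine genes 12 rose (13 adjusted over the list alone), with Ccl7, a monocyte attractant, at least 10.9-fold and its receptor Ccr2 at least 7.12-fold higher. Of 18 antigen presentation genes 9 rose (13 adjusted over the list alone), among them H2-Ab1 (8.76-fold), H2-DMa (7.24-fold) and H2-Aa (6.47-fold). Of 11 complement genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). C1qb (9.68-fold), which like C1qa and C1qc is also on the macrophage list, and C3ar1 (7.81-fold) led. These 3 lists also passed camera with an estimated correlation (adjusted p = 0.00622, 0.035 and 0.0284). On the brightest probe set of each gene none of 9 lymphocyte genes passed, adjusted either way, while another probe set of Ighm, an antibody gene, was 2.02-fold lower (338 ± 119 against 659 ± 54.3, limma adjusted p = 0.00389); 1 of 6 neutrophil genes did, S100a8 (2.65-fold higher). Of 15 interferon induced genes 2 rose (2 adjusted over the list alone), Ifi204 (2.23-fold) and Ifi27l2a (1.63-fold), and the list did not pass camera (adjusted p = 0.161). Without leg control 1 and 4, an alternative added after seeing the data, 28 macrophage, 8 cytokine, 12 antigen presentation and 6 complement genes rose.

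Matrix, cell cycle and regeneration genes also rose. Of 44 matrix genes 31 rose and 0 fell (32 adjusted over the list alone; adjusted p = 0.0284 with an estimated correlation), with Mmp3 at least 7.70-fold, Timp1 5.63-fold and Bgn 4.45-fold higher. Of 24 cell cycle genes 12 rose (12 adjusted over the list alone; adjusted p = 0.0284 with an estimated correlation), with Cks1b at least 7.55-fold and Ccna2 4.97-fold higher. Among 30 satellite cell and myogenic genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation); Id2 was 5.08-fold, Peg3 4.15-fold and Igf2 3.07-fold higher. Among 17 embryonic and denervation type genes 6 rose and 1 fell (7 and 3 adjusted over the list alone; adjusted p = 0.0491 with an estimated correlation), with Ankrd1 11.5-fold, Tnnt2 4.69-fold and the acetylcholine receptor gene Chrna1 4.32-fold higher. Of 28 proteolysis genes 10 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), and the lysosomal proteases Lgmn (4.94-fold) and Ctsz (4.39-fold) led. Of 23 immediate early and heat shock genes 6 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation), with Junb at least 8.56-fold higher on 1 of its 2 probe sets, both of which passed. Without leg control 1 and 4 the rises numbered 26 in the matrix, 9 in the cell cycle, 10 in the satellite cell and 5 in the embryonic type list. Embryonic Myh3 did not pass (383 ± 202 against 607 ± 129, limma adjusted p = 0.116), nor did Utrn, the dystrophin relative (266 ± 67.4 against 191 ± 47.8, limma adjusted p = 0.502).

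Genes of energy metabolism fell in mdx leg muscle. Of 21 fatty acid oxidation genes 14 fell and 0 rose (18 adjusted over the list alone; median log2 difference -0.53, adjusted p = 0.0284 with an estimated correlation). Eci1 was 1.70-fold, Hadh 1.68-fold and Ech1 1.64-fold lower. Of 22 glycogen and glycolysis genes 9 fell (9 adjusted over the list alone; adjusted p = 0.0891 with an estimated correlation), with hexokinase Hk2 1.92-fold and the glucose transporter Slc2a4 1.66-fold lower. Of 53 oxidative phosphorylation genes 19 fell and 1 rose (27 and 1 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), and without leg control 1 and 4, 6 fell and 1 rose. In the fatty acid oxidation and glycolysis lists 11 and 7 then fell. Of 16 fast fibre genes 3 fell, Phkg1, Pfkm and Gpd1 (4 adjusted over the list alone, adjusted p = 0.548 with an estimated correlation). All 3 are also on the glycogen and glycolysis list. The Pfkm and Gpd1 calls ended in 1 and 2 of the 10 fits without 1 array (limma adjusted p of up to 0.0542 and 0.0668). The dystrophin complex list of 17 genes held 4 falls, among them Sgca (1.53-fold) and Dag1 (1.32-fold), and 1 rise, of Itga7. The Itga7 log2 difference was 0.59 (limma adjusted p = 0.053 without leg control 4). Adjusted over the list alone this list held 5 falls and 1 rise, and without leg control 1 and 4 it held 1 and 0. No adipocyte gene of 10 or nerve gene of 9 passed on its brightest probe set, adjusted either way. No slow fibre gene of 13 passed either, but 2 fell without those arrays. Of 18 calcium handling genes 2 fell (2 adjusted over the list alone), and 1 without those arrays. The falls in the complement and embryonic type lists were then 0 each, and those in the proteolysis and immediate early lists 1 each.

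In all, 1287 of 7204 probe sets passed in leg muscle, 772 higher and 515 lower in mdx, and 491 differed at least 2-fold, 430 of them higher. The 2 groups' arrays did not overlap for 13.6% of probe sets, against 0.794% by chance. Without the array labelled leg control 4 the count was 1180, and without leg control 1 and 4 it was 958. The 3' over 5' ratio of the beta-actin control probe sets, a common check of RNA integrity, differed between the leg groups: log2 -1.86 ± 1.25 in mdx against 0.50 ± 0.37 in control arrays (exact permutation test, two-sided, p = 0.0079, the smallest possible, n = 5). The same ratio of Gapdh did not differ detectably (-2.50 ± 0.14 against -2.48 ± 0.84, exact permutation p = 0.93). Of the beta-actin probe sets the 3' one was lower in mdx leg arrays (log2 difference -2.30, limma adjusted p = 0.00838 over the control probe sets). The 5' and middle ones were not detectably changed (0.06 and 0.23), so the lower ratio came from the 3' probe set and does not by itself show a difference in RNA integrity. Control and mdx arrays carry different description labels within each muscle, so any batch that goes with these labels cannot be told apart from genotype.

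**Figure D1:**
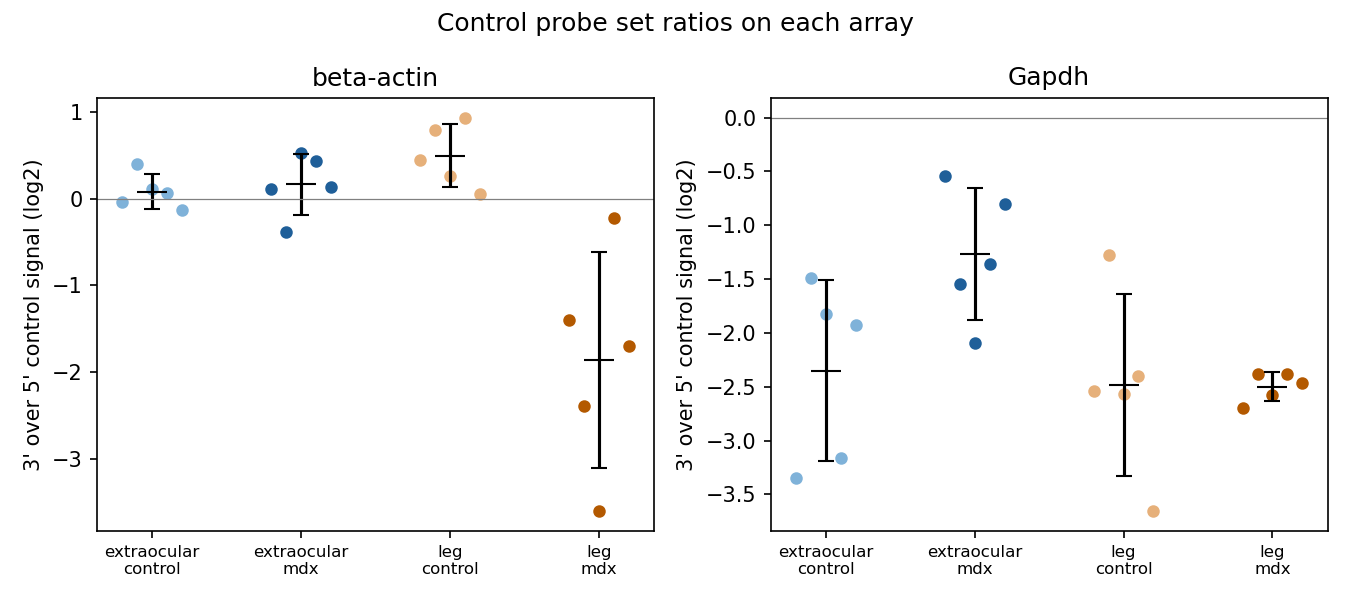
Log2 ratio of 3' over 5' control probe set signal of beta-actin (left) and Gapdh (right) on each of the 20 arrays, by group; points are arrays, black bars the mean ± SD of 5. The leg mdx arrays have the lowest mean beta-actin ratio, -1.86.

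The second comparison asked the same of extraocular muscle, where 5 named genes passed. Mt2, a metal-binding metallothionein, was 2.53-fold higher in mdx (6440 ± 1268 against 2598 ± 816, limma adjusted p = 0.00221). Krt6a, an epithelial keratin, was 4.96-fold higher (866 ± 521 against 158 ± 64.7, limma adjusted p = 0.0259) and Ctss 2.06-fold higher (1414 ± 363 against 686 ± 183, limma adjusted p = 0.0259). Erdr1 was 2.82-fold lower (717 ± 163 against 1995 ± 242, limma adjusted p = 0.000195) and AI506816 2.57-fold lower (limma adjusted p = 0.017). That all 5 mdx arrays lay beyond all 5 controls was a condition for choosing these 5 genes. The 2 groups' arrays did not overlap for 1.15% of all tested probe sets, against 0.794% by chance. The sixth passing probe set, lower in mdx, matches several genes and is not named.

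Macrophage genes in extraocular muscle had a median log2 difference of 0.41, but only Ctss of the 30 passed (4 adjusted over the list alone). Lgals3 was at 317 ± 185 against 69.0 ± 37.4 (limma adjusted p = 0.104) and Ccl2 at 320 ± 90.2 against 112 ± 65.1 (limma adjusted p = 0.156). The macrophage list passed camera with the preset correlation (adjusted p = 1.01e-07) and not otherwise (adjusted p = 0.17 with an estimated correlation). The same held for cytokines (adjusted p = 0.17 with an estimated correlation), satellite cell genes (0.0584 so computed), immediate early genes (0.318) and interferon induced genes, whose median was -0.43 (0.318). Adjusted over the list alone, 1 cytokine gene rose, 1 interferon gene fell, and no satellite cell or immediate early gene passed. No matrix gene of 44, fatty acid oxidation gene of 21 or cell cycle gene of 24 passed; adjusted over the list alone 1 matrix gene and none of the others did. The matrix list had a median of -0.04 and a mean of 0.03. Utrn was at 213 ± 108 against 258 ± 104 and Myh3 at 338 ± 158 against 539 ± 177 (limma adjusted p = 0.999 and 0.958).

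The extraocular count of 6 probe sets, 3 higher and 3 lower, compares with 369 at an unadjusted p under 0.05, where chance gives 360. It was 3 without extraocular control 2, control 3 or mdx 5, and 11 without extraocular mdx 3. The Krt6a, Ctss and AI506816 calls ended in 7, 6 and 5 of the 10 fits without 1 array (adjusted p of up to 0.133, 0.133 and 0.0992), and also without a filter (0.151, 0.136 and 0.136).

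**Figure D2:**
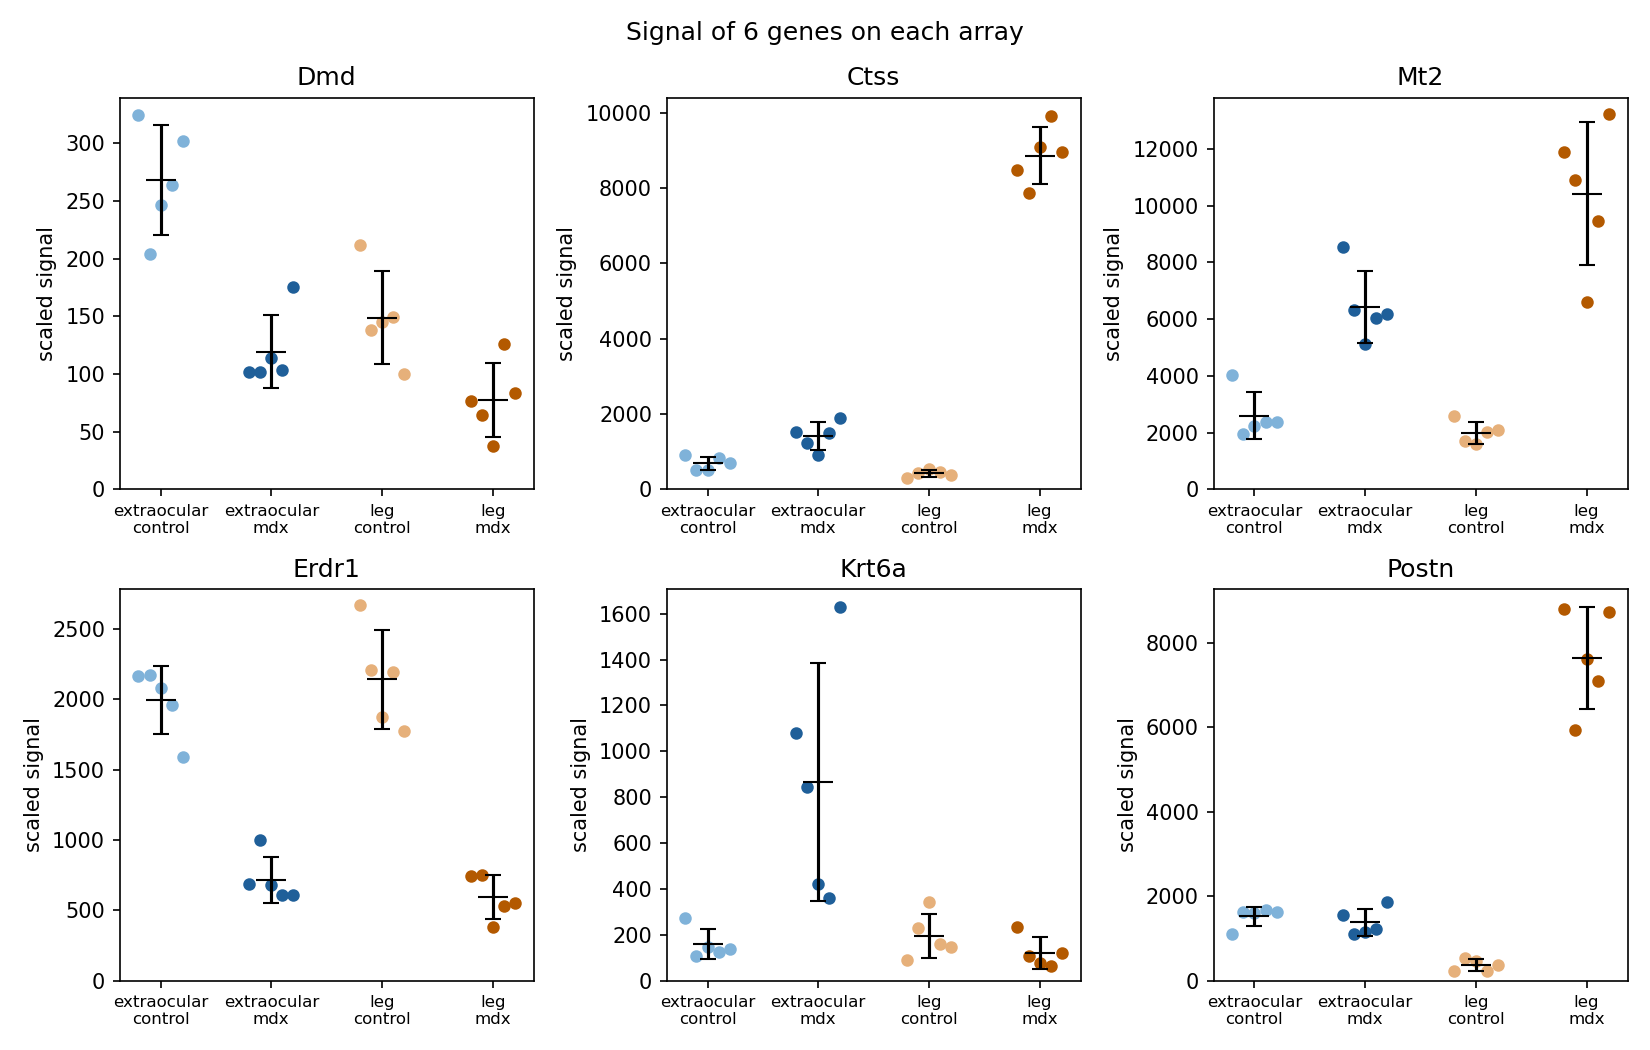
Scaled signal (linear axis from 0) of Dmd, Ctss, Mt2, Erdr1, Krt6a and Postn on each array, by group; points are arrays, black bars the mean ± SD of 5. Ctss averages 8856 in leg mdx and 1414 in extraocular mdx arrays, while Erdr1 is lower in mdx arrays of both muscles.

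The third comparison tested whether the mdx effect differs between the muscles. It did for Postn, whose effect was 4.64 log2 units larger in leg than in extraocular muscle (SE 0.31, limma adjusted p = 4.52e-09), and for Mmp12 (4.23), Ccl8 (3.80), Lyz2 (3.69), Lgals3 (3.69), Cd53 (3.68), Lcp1 (3.59) and C1qtnf3 (3.58). Ctss, which rose in both muscles, rose 10.3-fold more in leg. Rpl41 (-4.03), Krt6a (-3.01), Nkx1-2 (-2.46), Ces1d (-2.41), Sfn (-2.31), Crhr2 (-2.21), Wnt4 (-2.07) and Ndp (-2.02) had the effects most negative in leg relative to extraocular muscle. The Wnt4 and Ndp calls ended in 10 and 11 of the 20 fits without 1 array, with an adjusted p of up to 0.0664 and 0.0708. Erdr1 fell in both muscles, with no detected difference between them (-0.39, limma adjusted p = 0.447). Of these genes Mmp12, Ccl8, Lgals3, Cd53, C1qtnf3, Nkx1-2, Ces1d, Sfn, Crhr2, Wnt4 and Ndp had arrays at the floor, so their sizes depend on it. The mean 3' over 5' ratio of the control genes was lower in mdx leg arrays and higher in mdx extraocular arrays (log2 differences -1.19 and 0.58, exact permutation p = 0.016 and 0.056), so this ratio moves with the contrast. In leg muscle the Gapdh ratio alone differed by -0.02 (exact permutation p = 0.93), so the mean does not show that RNA integrity moved with it.

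By list, the leg effect was the more positive for 24 of 30 macrophage genes (28 adjusted over the list alone), 20 of 44 matrix genes (29), 7 of 18 antigen presentation genes (11), 7 of 16 cytokine genes (8), 5 of 11 complement genes (7) and 8 of 24 cell cycle genes (11). These 6 lists passed camera with an estimated correlation, with adjusted p between 0.00179 and 0.0401. Without leg control 1 and 4 the matrix count was 16 and the cell cycle count 3. For fatty acid oxidation the leg effect was the more negative in 4 of 21 genes (9 adjusted over the list alone; adjusted p = 0.0401 with an estimated correlation), and 3 without leg control 1 and 4. The Ech1 and Crat calls passed in all 20 fits without 1 array, while those of Hadh and Eci1 ended in 10 and 6 of them (adjusted p of up to 0.0703 and 0.0688). Glycolysis held 2 of 22 genes with a more negative leg effect and oxidative phosphorylation 3 of 53 (5 and 6 adjusted over the list alone; adjusted p = 0.0789 and 0.14 with an estimated correlation). Of the latter, the Ndufb6 and Ndufs4 calls ended in 13 and 17 of the 20 fits without 1 array (adjusted p of up to 0.0895 and 0.084). Interferon induced, fast fibre, calcium handling and proteolysis genes passed camera with the preset correlation and not otherwise (adjusted p = 0.251, 0.346, 0.132 and 0.157 with an estimated correlation). In all, 448 probe sets passed, 355 with the more positive effect in leg muscle; without leg control 4 the count was 459, and without leg control 1 and 4 it was 364.

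**Figure D3:**
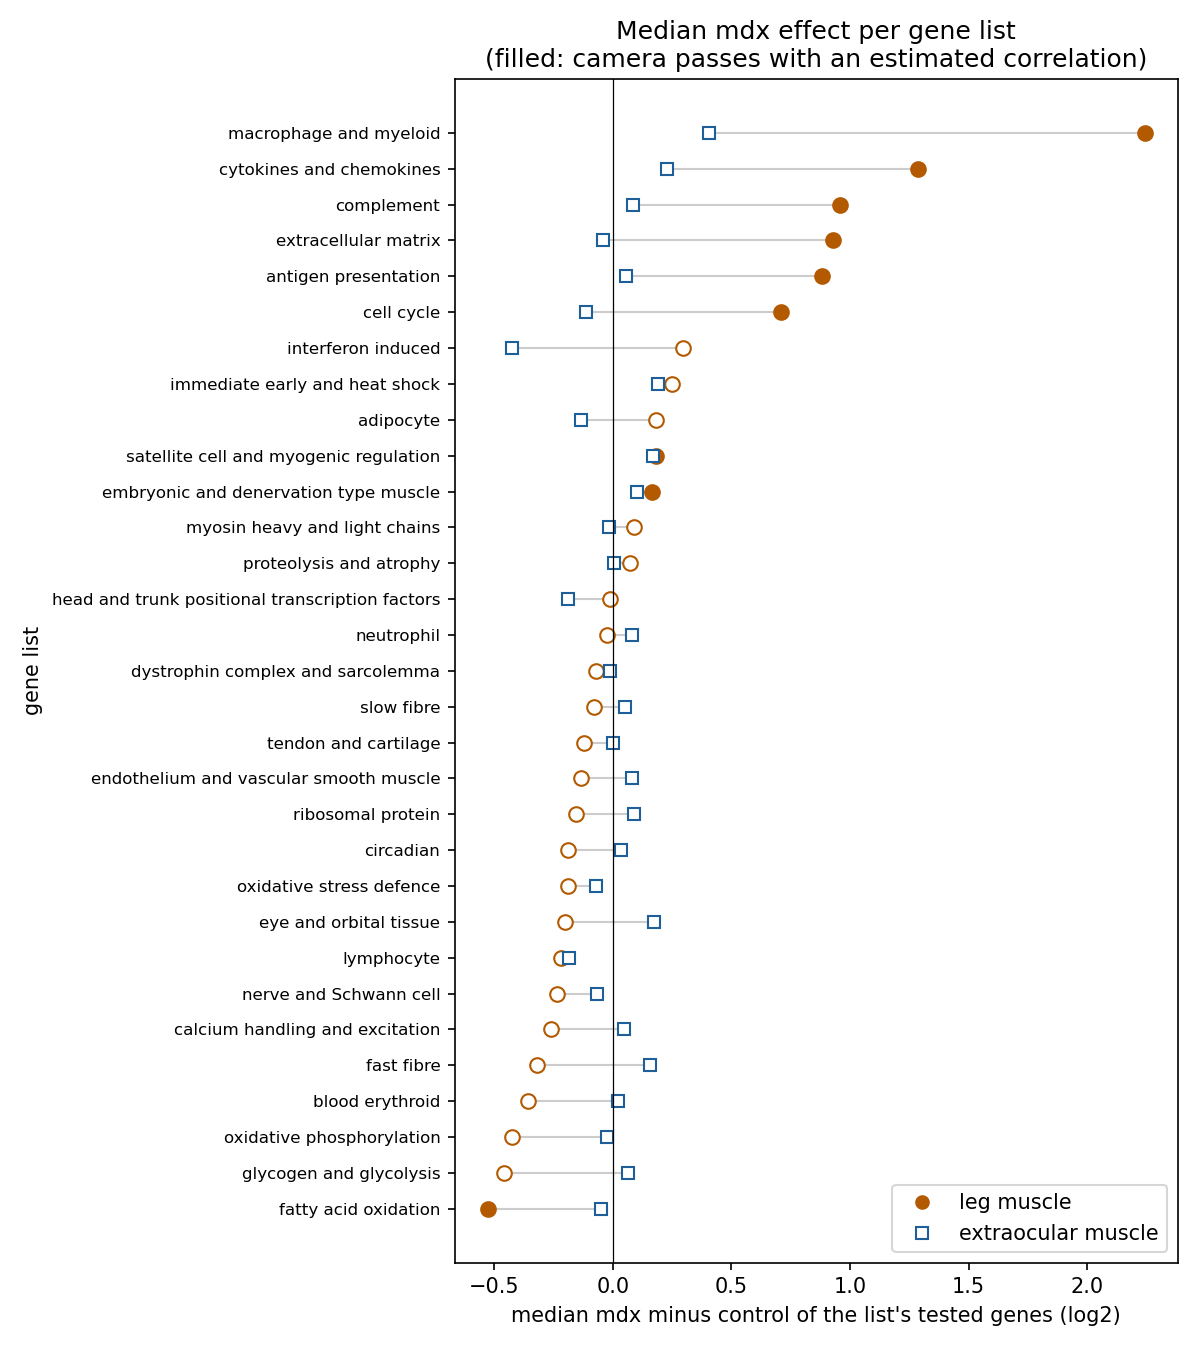
Median mdx minus control log2 difference of each gene list in leg muscle (circles) and extraocular muscle (squares); filled symbols pass camera with an estimated correlation. The macrophage list has a median of 2.24 in leg and 0.41 in extraocular muscle, and no extraocular symbol is filled.

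Across all 7204 probe sets the mdx effects in the 2 muscles correlated weakly (Pearson r = 0.211, Spearman rho = 0.174). Of 100 reassignments of genotype within each muscle none gave an r as large in size, the highest being 0.196 (permutation p = 0.0099, the smallest these can give); probe sets are not independent replicates. The probe sets higher in mdx leg muscle had a mean effect of 1.30 there and 0.12 in extraocular muscle, where 66.8% were positive. Control and mdx arrays carry different description labels in both muscles, so a batch that goes with these labels could also give such a correlation.

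**Figure D4:**
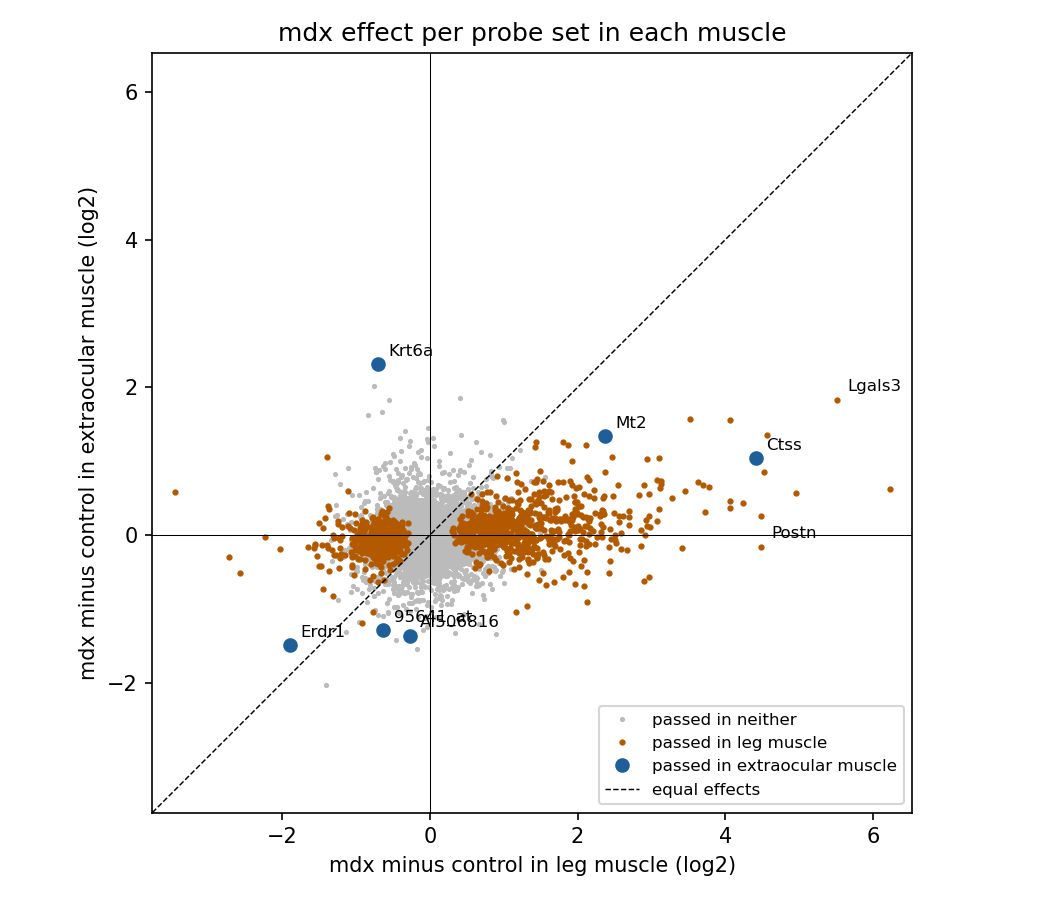
Log2 mdx minus control difference of each of 7204 probe sets in leg muscle (horizontal) and extraocular muscle (vertical); colours mark probe sets that passed in neither, in leg or in extraocular muscle, and the dashed line marks equal effects. Lgals3 and Postn lie far to the right and near the horizontal axis compared with the dashed line.

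The fourth comparison set extraocular against leg muscle in control mice. Myom2, a protein of the sarcomere's M-band, was at least 44.9-fold lower in extraocular muscle (39.9 ± 33.0 against 2606 ± 561, limma adjusted p = 2.36e-12), and the calcium channel subunit Cacng1 12.7-fold lower (398 ± 91.1 against 5093 ± 1388). Styx, Dnajb5, Atp1b2, Tspan8, Abcf2 and Slc38a4 were between 4.85 and 5.48-fold lower (at least so for Atp1b2). The adult acetylcholine receptor subunit Chrne was at least 10.3-fold higher (1114 ± 159 against 121 ± 94.1, limma adjusted p = 4.69e-06), as were Frzb (at least 9.91-fold), the anion exchanger Slc4a3 (8.67-fold), Inha (8.02-fold), the potassium channel Kcna1 (at least 7.38-fold) and Cyfip2 (at least 7.04-fold). Csrp2 and Cyp1b1, at the floor on all leg control arrays, were at least 9.76-fold and at least 7.98-fold higher.

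Several groups differed between the control muscles, though no list passed camera with an estimated correlation. Of 44 matrix genes 20 were higher and 1 lower in extraocular muscle (22 and 2 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation; 15 and 2 without leg control 1 and 4), with Postn 4.43-fold and elastin Eln 3.12-fold higher. Of 19 endothelial and vascular smooth muscle genes 6 were higher (8 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), led by Myh11 (5.60-fold). Of 9 nerve and Schwann cell genes 4 were higher (4 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation), with the myelin genes Pmp22 4.76-fold and Mbp 3.08-fold higher. Of 22 glycogen and glycolysis genes 8 were lower and 1 higher (8 and 3 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation; 7 and 3 without leg control 1 and 4), with Phka1 4.32-fold and Fbp2 3.93-fold lower. Of 16 fast fibre genes 4 were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation). Gpd1, which is also on the glycogen and glycolysis list, was 3.50-fold and parvalbumin Pvalb 2.76-fold lower. Of 21 fatty acid oxidation genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.485 with an estimated correlation). Chrna1 was 6.03-fold, Peg3 4.86-fold and Stmn1 at least 5.27-fold higher, and Hoxc9 4.02-fold and En1 at least 4.00-fold lower. In all 1275 probe sets passed, 741 higher and 534 lower in extraocular muscle; without the array labelled leg control 4 the count was 1232.

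The last comparison set the muscles against each other in mdx mice. Bpifa2 was 15.5-fold, Slc4a3 9.14-fold and Crhr2 at least 9.05-fold higher in extraocular muscle, and Rpl41 9.15-fold. Myom2 was 18.5-fold, Mmp12 14.8-fold, Cd53 at least 14.8-fold and Lgals3 12.0-fold lower. Of 30 macrophage genes 28 were lower (29 adjusted over the list alone; adjusted p = 0.00578 with an estimated correlation), and 9 of 16 cytokine genes (9 adjusted over the list alone; adjusted p = 0.0489 with an estimated correlation). Of 21 fatty acid oxidation genes 17 were higher and 0 lower (18 adjusted over the list alone; adjusted p = 0.0174 with an estimated correlation). Of 53 oxidative phosphorylation genes 22 were higher (25 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation). Of the immune lists, 7 of 18 antigen presentation genes (9 adjusted over the list alone), 7 of 11 complement genes (7) and 2 of 15 interferon induced genes (2) were lower, as were 12 of 44 matrix genes (15), 8 of 24 cell cycle genes (17) and 10 of 28 proteolysis genes (10). In the other direction 4 matrix genes were higher, Fbln1 by 3.60-fold on 1 of its probe sets, as were 1 cell cycle and 1 complement gene. With leg control 1 and 4 left out of the shared estimate of spread, 20 matrix genes were lower. Of 19 endothelial and smooth muscle genes 10 were higher and 1 lower (12 and 1 adjusted over the list alone), and 4 of 9 nerve genes (4). These 8 lists passed camera with the preset correlation and not otherwise (adjusted p from 0.0511 to 0.662 with an estimated correlation). Myh8 was 1.69-fold higher, and Myh4 2.01-fold on 1 of its 2 probe sets (limma adjusted p = 0.0293; 1.09-fold and 0.831 on the other), a call that ended in 4 of the 10 fits without 1 array (adjusted p of up to 0.0921, without leg mdx 3). In all 1302 probe sets passed, 666 higher and 636 lower; the 3' over 5' ratios of beta-actin and of Gapdh both differed between these groups (log2 differences 2.03 and 1.23, exact permutation p = 0.016 and 0.0079, adjusted 0.0384 and 0.0316). Between the muscles, 282 probe sets were higher and 208 lower in extraocular muscle in both genotypes, where independent lists would share 68.5 and 47.1, and 52 passed in opposite directions.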

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

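The tests of array spread, of a broad technical difference, of dilution and of the array labelled leg control 4 were chosen after the results were seen; the splits, the test of a smaller shared response and the scaling test were set before. The rules for dilution and for the keratins were also tightened after a first value had been seen. This left the outcome of the dilution rule as it was and turned the keratin one from excluded to undecided. The dilution outcome is not used as a verdict below, for a reason given there.

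The mdx effect differed between leg and extraocular muscle for 448 probe sets, by a test of the difference itself. The largest differences in log2 units, leg minus extraocular, were Postn 4.64, Mmp12 4.23, Ccl8 3.80, Lyz2 3.69, Lgals3 3.69, Cd53 3.68, Lcp1 3.59 and C1qtnf3 3.58, and on the other side Rpl41 -4.03, Krt6a -3.01, Nkx1-2 -2.46, Ces1d -2.41, Sfn -2.31, Crhr2 -2.21, Wnt4 -2.07 and Ndp -2.02.

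Many probe sets passed in leg muscle (1287) and few in extraocular muscle (6). A larger spread between extraocular arrays is argued against, since their median within-group SD was 0.925 times that of the leg arrays. A technical difference shared by all control and all mdx arrays is argued against as the whole cause, since extraocular calls were 0.466% of leg calls; a batch within leg muscle alone cannot be told apart from genotype. A smaller response of the same genes stays possible, as leg-raised probe sets had a mean extraocular effect of 0.121. An exact permutation test over splits of the extraocular arrays gave a one-sided p = 0.0079, and 1 other split gave more, 0.126. A small technical difference shared by all control and all mdx arrays would give such a shift too, so this test does not tell the 2 apart. A difference in RNA or array quality stays open. The mean 3' over 5' ratio differed by -1.19 log2 units between mdx and control in leg and by 0.58 in extraocular muscle. In leg muscle this came from beta-actin (-2.37), while Gapdh differed by -0.02 (exact permutation p = 0.93), so the ratio does not show poorer RNA integrity. The muscle, the design's own difference, also stays open as a hypothesis.

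Other splits of the arrays were compared by the count of passing probe sets, 100 splits each with the real one included. For leg muscle 1 split, the real one, reached 1287 (highest other 302). For extraocular muscle 1 reached 6 (highest other 2), for the muscles in control mice 1 reached 1275 (highest other 144) and in mdx mice 1 reached 1302 (highest other 9). For the difference of effects 2 of 100 reached 448, and the other gave 710. That split kept the labels of all 10 leg arrays and mixed those of extraocular muscle, so it points to a structure of the samples, the leg difference itself. A chance division of the arrays is argued against at this number of splits for the other 4 counts. For extraocular muscle this rests on 6 calls, and 369 probe sets had an unadjusted limma p under 0.05, where chance gives 360. A chance division is therefore not excluded for the extraocular count. For the difference of effects 2 of 100 is also a small share, but splits that mix the leg labels undo the leg difference as well, so the share does not test the difference of effects apart from it.

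Metabolic genes had lower signal in mdx leg muscle. Dilution of muscle RNA by RNA of infiltrating cells lowers all fibre genes alike, yet the fatty acid oxidation score differed from the fibre score by -0.38 log2 units (exact permutation p = 0.032). The difference was -0.37 without leg control 1 and 4 (exact permutation p = 0.018) and -0.41 without probe sets of very high signal (exact permutation p = 0.0079). The scores thus did not fall alike. The fibre score itself differed by -0.168 (exact permutation p = 0.4). It included the dystrophin complex list, not all of whose genes are confined to fibres, so infiltrating cells may hold it up. How much of the fall dilution explains was therefore not settled. A scaling factor shared by all probe sets of an array is argued against as the whole cause, since camera compares the fatty acid oxidation list with the other genes. The list also passed after quantile normalization (camera adjusted p = 9.22e-08 with the preset correlation). A change in the fibres or in their types stays open as a hypothesis, and so does a batch that goes with genotype.

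The array labelled leg control 4 stood apart from the other leg controls, and was tested on the 8 positional probe sets of the fixed list that differed between the muscles in mdx mice. Several of these probe sets are of the same gene, Tbx15, so they are not independent. On a scale from the leg mdx level to the extraocular mdx level their median position was 0.95 on this array and at most 0.18 on the other leg controls, which argues against hindlimb muscle that only lacks its slow part. The 4 probe sets higher in leg muscle had a median ratio of 0.302 to the other leg controls, which argues against a minor admixture of other tissue. A candidate explanation is a muscle of another body region under this label: 75.0% of the positional probe sets lay nearer to the extraocular level, against at most 25.0% on the other leg controls. Its slow fibre score of 9.06, against 11.43 to 11.78 in extraocular arrays, argues against an exchange with those; which muscle it was is untested, and Six2 went the other way (1839 against 1070 to 1271).

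The test for a single array far from the other 4 of its group was met in 20 of 204 groups, where chance gives 10.2. For Kcna1, Crhr2 and Myom2 below the other 4 arrays all lay at the floor, which alone fixes the outcome, so these 3 are no evidence of a distant array. In the 196 groups with fewer than 4 arrays at the floor 17 met it, where chance gives 9.8. In leg control arrays these were Mmp12 203 and Frzb 105 (array 3), Ccl8 200 (array 5), Aqp4 1221 (array 1), Gdap1 519 (array 2) and Kcna1 55.9 (array 4). In leg mdx arrays they were Crhr2 53.8 and Cyp1b1 191 (array 5) and Lcp1 1134 (array 3). In extraocular control arrays they were Postn 1105, Mt2 4025, C1qtnf3 85.4 and Myom2 96.4 (array 1), Utrn 87.8, Myh8 421 and AI506816 629 (array 5) and Tspan8 56.8 (array 4). In extraocular mdx arrays they were Mmp12 226 and Dmd 175 (array 5) and Erdr1 999.9 (array 2).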

How the results depend on the processing

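The fits without leg control 1 and 4 were chosen after the results were seen; the other alternatives were fixed in advance. The counts of passing probe sets for leg muscle, for the difference of effects and between the muscles stayed within 1.5 times their values under every alternative run. The extraocular count of 6 became 11 with a floor of 100 and with array weights, and 3 without a filter; leaving out 1 array gave 3 to 11. The correlation of the mdx effects, 0.211, became 0.291 with the filter at 500. Lists that passed camera numbered 14 in leg muscle, 5 in extraocular muscle, 13 for the difference, and 6 and 12 between the muscles in control and mdx mice. With an estimated correlation these were 9, 0, 7, 0 and 3. With fry the extraocular number was 0 and that between control muscles 16; fry does not compare a list with other genes. Without a filter 3 extraocular lists passed, and without leg control 1 and 4, added after seeing the data, 3 between control muscles. The leg difference of the 3' over 5' ratio, -1.19 for the mean of both genes, was -0.02 for Gapdh alone. Except where stated, the cause was not tested. No result reversed. With a replicate block the counts were 1351, 7, 458, 1351 and 1386, the correlation 0.211 and the lists 13, 5, 12, 7 and 12. The block ended the calls of the immediate early list in leg muscle (adjusted p = 0.0502) and of the proteolysis list for the difference (0.0621), and added the adipocyte list between control muscles (0.0491). Same-numbered arrays correlated between -0.08 and 0.23. Within each muscle 3 of 5 control arrays correlated best with the mdx array of their own number, with a mean of 0.10 against -0.02 for other pairs. Whether the numbers pair the arrays was left open. Genes near the floor of 50 have only compressed folds.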

Other observations

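The keratin test was chosen after the Krt6a result was seen, and the test of baseline levels before.

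Nr1d1, a repressor in the circadian clock, was 2.02-fold lower in mdx leg muscle (1123 ± 184 against 2301 ± 522, limma adjusted p = 3.26e-05) and 1.59-fold lower in extraocular than in leg muscle of control mice; it was the 1 passing gene of 10 circadian genes in leg mdx (1 adjusted over the list alone). Mt2 rose 5.17-fold and Mt1 3.70-fold in mdx leg muscle, and the Mt2 rise was larger in leg than in extraocular muscle (limma adjusted p = 0.029), a call that ended in 5 of the 20 fits without 1 array. Among 25 oxidative stress genes 5 rose and 3 fell in mdx leg muscle (5 and 3 adjusted over the list alone; 3 and 1 without leg control 1 and 4), and the list did not pass camera (adjusted p = 0.964; median -0.19, mean 0.08).

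Bpifa2 lay between 3030 and 4634 on all 10 extraocular arrays and between 78.1 and 828 on the leg arrays other than leg control 4. Beside Krt6a, the other epithelial keratins of the eye list differed by 0.31 log2 units between mdx and control extraocular arrays (exact permutation p = 0.27, upper 95% bound 0.85), so that surface epithelium in the mdx samples was neither shown nor excluded, with Krt4 at 1335 against 987, Krt13 at 232 against 115, Krt12 at 251 against 235, and Krt5 and Krt14 near the floor.

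A hypothesis is that part of what rises in mdx leg muscle is already high in control extraocular muscle, as Postn and Chrna1 are. The 5 leg control arrays were split in the 10 ways that leave 3 and 2, so that the mdx comparison and the muscle comparison shared no array. Probe sets called higher in mdx leg muscle had a median extraocular minus leg difference in control mice of 0.462 log2 units on average over the splits, against a median of at most 0.031 for random sets matched on signal. The matching used the mean of the leg control and leg mdx arrays of each call. Probe sets called higher in mdx therefore tend to have lower leg control signal than their matches, which alone can make this difference positive. The test thus does not decide the hypothesis. A batch shared by all leg control arrays could also give the same result, and the array labelled leg control 4 is among them.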
